A study of Trichoderma reesei with 18 samples.

How the data were processed

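RNA sequencing had been carried out on mycelium of the filamentous fungus Trichoderma reesei, a cellulase producer, in 18 libraries. Strains were the wild type QM6a (WT) and deletion mutants of the genes TR80186 and TR21168, called Δ80186 and Δ21168 here. The series title names both genes as MAP kinase kinases, of the HOG (osmotic stress) and pheromone signalling cascades. Per the labels' protocols, each strain was grown for 96 h on cellulose as carbon source in constant darkness or constant light, and libraries were made with a strand-specific kit after depletion of ribosomal RNA. Each of the 6 groups held 3 libraries, assigned from the sample titles. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which can be technical.

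The deposited table held whole-number counts per gene, not normalised, with 1 column per library. Per the submitters' processing notes, reads were aligned with HISAT2 2.2.1, and the series design names a published QM6a transcript set. The strand setting of the counting, the treatment of reads with several alignments, trimming and the genome build are not given in the sources used here. Reads of overlapping neighbours, of antisense partners and of near-identical copies could therefore not be told apart. The table had 10879 rows, and 0 columns of per-sample values were left out. All columns were matched to samples by the sample descriptions.

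Of the 10879 row identifiers, 10876 were a letter code with a number and an ending W or C, and 3 were named after the mating type locus (mat1-1-1, mat1-1-2 and mat1-1-3). The reference table of assembly GCF_000167675.1 listed 9116 genes under other locus tags, and 0 of the identifiers were found in it. No gene names were taken from it. The gene lists fixed before the data were examined (cellulases, hemicellulases, light response, mating, MAP kinases, stress, transporters, secondary metabolism and others) had 0 lists with a matched member, so neither list counts nor list tests were run. For the same reason the deleted genes could not be looked up by their numbers, and the values of their annotated neighbours were not analysed here.

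Library totals ranged from 7945697 to 15672321 counts. Between 9414 and 9924 genes had at least 1 read in a library. Genes were kept with filterByExpr by group (minimum count 10, minimum total count 15), which left 9079 genes and removed 1800. The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, robust dispersion estimates and the quasi-likelihood F test, in 1 fit of all 18 libraries with a mean per group and 12 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, and genes with an adjusted p under 0.05 are called changed. The count with a fold of at least 2 is given beside it. Standard errors (SE) of fold changes are the absolute log2 fold change divided by the square root of the F statistic. For genes with few reads in a group this SE can be smaller than counting error, so it does not give their precision. CPM values are edgeR's, on TMM-scaled library sizes, given as mean ± SD of 3 libraries.

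There were 7 pairwise comparisons (each mutant against WT in each light condition, and light against darkness in each strain) and 2 interactions. An interaction is the log2 light response of a mutant minus that of WT. Named genes followed a rule set before the data were examined: genes with a mean of at least 5 CPM in the higher group and no overlap of the 3 values of each group, ranked by log2 fold change. As no identifier could be paired with a name, the fallback of the rule held, naming at most 2 identifiers that rose and 2 that fell per comparison. For the interactions, the 2 positive and the 2 negative identifiers with the smallest adjusted p were named. Where all libraries of a group had 0 reads of a gene, the fold is a lower bound against a floor of 3 reads over the group. Where a group had 1 to 3 reads in all, the ratio of pooled reads is given with a 95% counting interval. Floors and intervals cover counting error only.

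Counts of 9079 genes were simulated with the observed depths and 200 genes changed, as many up as down. The dispersion of each gene was that fitted over all groups together. In the group tested, the other genes took the means of no change. The test found 60% to 82% of 2-fold and 79% to 93% of 4-fold changes, depending on the comparison. Of its calls, 2.78% to 7.1% were unchanged genes. In the data 2778 to 5543 genes were called per comparison, so these rates need not hold there. The wider spread of the dark libraries of Δ21168 was not simulated, so the rates do not cover its effect on comparisons with that group. For the comparison of Δ80186 with WT in darkness, 79% of the 2-fold and 91% of the 4-fold changes were found. Replicate libraries were checked for duplicates by chi-square tests over genes with at least 20 reads. The statistic per degree of freedom was 4.37 to 85.47 in the 18 replicate pairs, so no pair agreed within sampling noise.

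The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, the replicate number as a block, a fit of only the groups compared, and each library left out in turn. Library totals without TMM and reads thinned to the smallest library were added after seeing the data. The overlap of the mutants' responses was set beside 20 simulations per light condition, in which the mutant libraries were redrawn from the WT means. Other splits of the libraries were counted for each comparison, and neighbouring identifiers were compared with 1000 permutations within their letter series.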

Results

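The data comprised 18 libraries of Trichoderma reesei grown on cellulose for 96 h, with 3 libraries of each of 6 groups: WT, Δ80186 and Δ21168, each in darkness and in light. Library totals were 11249966 to 15672321 counts in the 12 libraries of WT and Δ80186 and 7945697 to 12415791 in the 6 libraries of Δ21168. Rank correlations of counts between libraries of a group were 0.971 to 0.997. The first principal component held 52.1% of the variance and separated light from darkness. The second, with 18.2%, set Δ80186 in light apart from the other groups in light. Library numbers in the sample descriptions formed 2 series, with Δ21168 in a series of its own, so a library batch and the Δ21168 genotype could not be separated in comparisons with WT, and no within-batch value could be had. Both light conditions of Δ21168 belonged to the same series.

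The files do not pair the deleted genes' numbers with row identifiers. TrD0367C had 0 to 2 reads in the 6 libraries of Δ80186 and 751 to 2269 reads in the 12 others. TrE0746W had 0 reads in each of the 6 libraries of Δ21168, where the highest upper 95% counting limit was 0.52% of the WT level, and 987 to 1710 reads in the 12 others. In the count table each was the 1 identifier with at most 3 reads per library in all libraries of that mutant and at least 10 CPM, here without TMM factors, in each of the others. Both were singled out by this loss of reads, so it is no independent check of the labels.

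**Figure D1:**
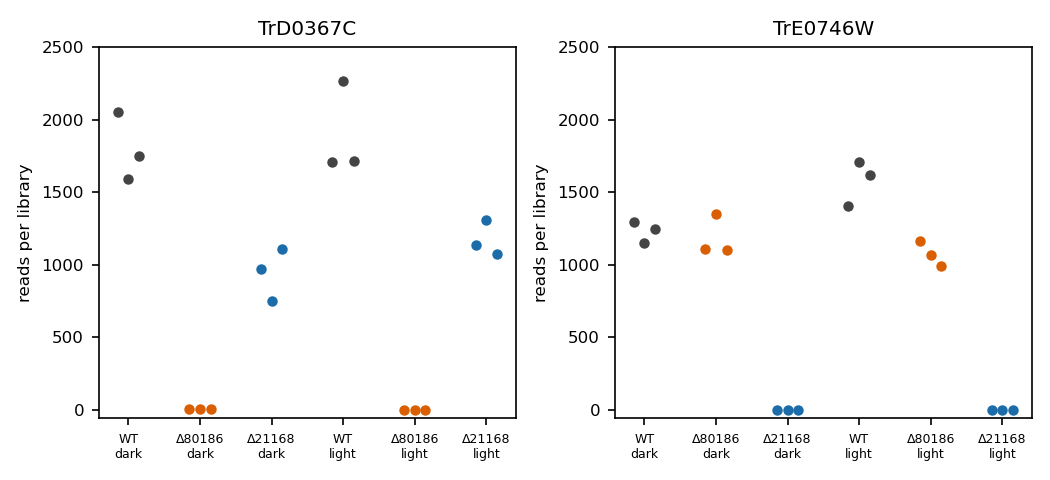
Reads per library (vertical axis) of TrD0367C and TrE0746W in the 6 groups, with 1 point per library and 3 libraries per group. TrD0367C lies at 0 to 2 reads in Δ80186 and TrE0746W at 0 reads in Δ21168, and they lie at 751 or more and at 987 or more reads in the other libraries.

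Light against darkness in WT addressed how illumination changes the transcriptome on cellulose. TrE0391W, which became one of the abundant transcripts, rose from 20.1 ± 12.8 CPM in darkness to 43500 ± 2300 CPM in light (log2 fold change 11.08 ± 0.60 SE, adjusted p = 3.5e-09; 11.69 without dark replicate 1). TrE0014C had 0 reads in all 3 dark libraries and 256 to 599 reads in light, at least 434-fold higher (281 without dark replicate 1, 289 without dark replicate 3). In the other direction, TrA0865C fell from 85.9 ± 11.3 CPM to 0 reads in all 3 light libraries, at least 1160-fold lower (711 without light replicate 2, 757 without light replicate 3). TrF0083C fell from 184 ± 42.6 CPM to 1 read in the 3 light libraries together, a pooled ratio of 7380 (95% counting interval 1330 to 292000). The ratio was 4540 without light replicate 2, and at least 1610 without light replicate 3, which held the read. Of 9079 genes tested, 5543 changed, 2947 higher and 2596 lower in light, but 2523 higher and 2950 lower with DESeq2. Among changes of at least 2-fold, lower genes prevailed under all alternatives, with 1407 lower and 775 higher in the main test.

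Light against darkness in Δ80186 addressed the same response without TR80186. TrB0209C rose from 1.98 ± 0.71 CPM to 3560 ± 241 CPM (log2 fold change 10.81 ± 0.62 SE, adjusted p = 9.7e-09), and TrE0645C rose from 0.0951 ± 0.0825 to 108 ± 21.4 CPM (10.05 ± 0.61 SE, adjusted p = 5.6e-09; 9.46 without dark replicate 2). TrA2144C fell from 36.4 ± 4.46 CPM to 0 reads in the 3 light libraries, at least 431-fold lower (276 without light replicate 1), and TrC0296W fell from 430 ± 80.7 to 0.144 ± 0.178 CPM (−11.49 ± 0.34 SE, adjusted p = 9.1e-13). The log2 fold change of TrC0296W was −10.88 without light replicate 1 and −13.02 without light replicate 3. It had 0 to 4 reads per light library, and its SE of 0.34 understates this spread. In all, 4836 genes changed, 2532 higher and 2304 lower, but 2376 higher and 2470 lower with DESeq2. Of these, 560 were at least 2-fold higher and 1213 at least 2-fold lower.

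Light against darkness in Δ21168 gave the corresponding response without TR21168. TrC1527C rose from 0.103 ± 0.0215 CPM to 200 ± 37.9 CPM, a pooled ratio of 1980 (95% counting interval 677 to 9610), and TrC0864C rose to 60.3 ± 1.03 CPM with a pooled ratio of 903 (250 to 7460). The ratio of TrC0864C was 536 without dark replicate 3, and at least 406 without dark replicate 1, which held the reads. TrA1899C fell from 81.4 ± 13.2 CPM to 0 reads in all 3 light libraries, at least 807-fold lower (510 without light replicate 2), and TrA2144C fell at least 541-fold (342 without light replicate 2). A total of 5469 genes changed, 2770 higher and 2699 lower (2425 and 3017 with DESeq2), with 664 at least 2-fold higher and 1298 at least 2-fold lower. Of the 3 dark libraries of this mutant, replicate 1 stood apart, with rank correlations of 0.971 to 0.976 with its own group. Without it, 5388 genes changed, and 4162 did in a fit of only the groups compared.

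**Figure D2:**
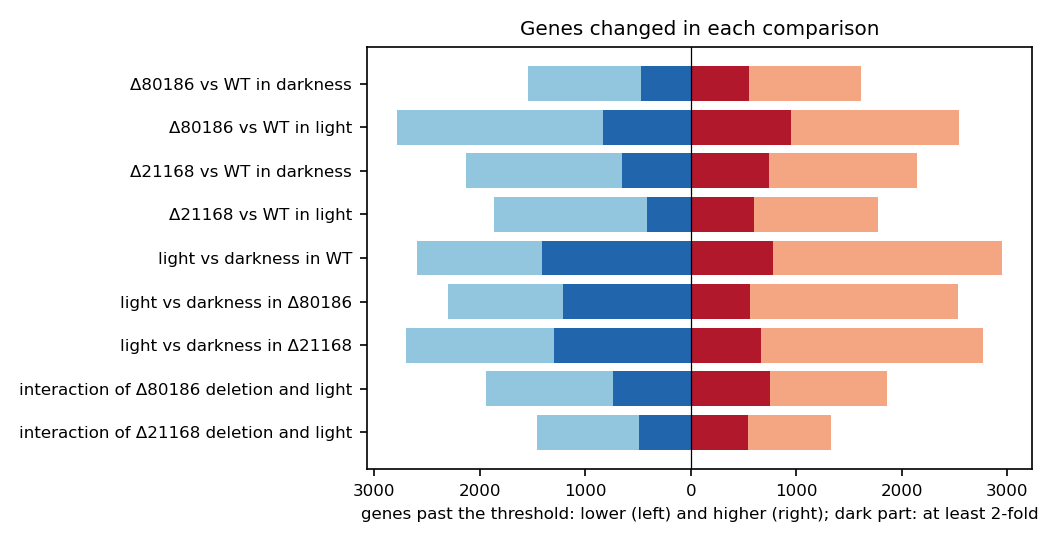
Number of genes with an adjusted p under 0.05 in each of the 7 pairwise comparisons and 2 interactions, lower to the left and higher to the right of 0, with changes of at least 2-fold in the darker shade. Light against darkness has more lower than higher genes among changes of at least 2-fold in each strain, 1407 against 775 in WT.

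Δ80186 against WT in darkness addressed the effect of the deletion without light. TrE0823C rose from 6 ± 2.51 CPM in WT to 866 ± 144 CPM in the mutant (log2 fold change 7.16 ± 0.48 SE, adjusted p = 1.6e-07), and TrD0072C rose from 0.792 ± 0.284 to 63.3 ± 3.57 CPM (6.29 ± 0.23 SE, adjusted p = 2.7e-12). TrD0367C fell from 131 ± 9.85 to 0.0932 ± 0.0458 CPM (−10.33 ± 0.18 SE, adjusted p = 3.9e-15). With 1 to 2 reads of TrD0367C per mutant library, this SE does not give the precision of the fold. TrG0638W had 0 reads in the 3 mutant libraries and 26 to 251 reads in WT, at least 135-fold lower (adjusted p = 0.0075). Its WT values spread widely: the bound was 69.2-fold without WT replicate 3 and 86.6-fold without mutant replicate 2. Its adjusted p was 0.067 in a fit of only the groups compared (range over 13 alternatives 4.2e-07 to 0.067). Altogether 3154 genes changed, 1611 higher and 1543 lower, with 554 at least 2-fold higher and 472 at least 2-fold lower.

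Δ80186 against WT in light addressed the same deletion under illumination. TrD0165W rose from 0.847 ± 0.652 to 128 ± 13.2 CPM (log2 fold change 7.23 ± 0.32 SE, adjusted p = 7.7e-11; 8.11 without WT replicate 3). TrD0609C rose to 5.25 ± 0.1 CPM with a pooled ratio of 212 (95% counting interval 37.6 to 8420), which was 130 without WT replicate 2. Without WT replicate 3, which held the 1 read, it was at least 46.3-fold higher. TrC1527C fell from 67.5 ± 36.7 to 0.0286 ± 0.0496 CPM, a pooled ratio of 2530 (454 to 1e+05). This ratio was 1620 without mutant replicate 1, and at least 569 without mutant replicate 3, which held the 1 read. TrD0367C was at least 1680-fold lower (1080 without mutant replicate 1). In this comparison 5328 genes changed, 2544 higher and 2784 lower, but 2803 higher and 2630 lower with DESeq2. Changes of at least 2-fold were found for 953 higher and 835 lower genes.

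Δ21168 against WT in darkness addressed the effect of the other deletion without light. TrB1819C rose to 17.4 ± 2.71 CPM, from 2 reads in the 3 WT libraries, a pooled ratio of 358 (95% counting interval 98.5 to 2960; 238 without WT replicate 3), and TrF0701C rose from 0.249 ± 0.163 to 33.3 ± 14.3 CPM (log2 fold change 7.03 ± 0.66 SE, adjusted p = 4.3e-07). TrE0746W was at least 893-fold lower (530 without mutant replicate 3). TrB1970W fell from 45.6 ± 19.5 to 0.179 ± 0.211 CPM (−7.77 ± 0.59 SE, adjusted p = 3.4e-08), and had a log2 fold change of −9.42 without mutant replicate 3, which held 5 of its 6 reads in the mutant. There were 4282 changed genes, 2148 higher and 2134 lower, of which 742 were at least 2-fold higher and 648 at least 2-fold lower. Without replicate 1 of the mutant, which stood apart, 4188 genes changed, and 3752 of the 4282 remained changed in the same direction. A fit of only the groups compared called 3133 genes, 1479 higher and 1654 lower, and kept 3094 of the 4282. The main fit estimates dispersion over all 6 groups together. The dark libraries of this mutant spread most, with a common biological coefficient of variation of 0.235, against 0.077 to 0.13 in the other groups.

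Δ21168 against WT in light completed the pairwise comparisons. TrB0848C had 0 reads in all 3 WT libraries and 5.54 ± 0.89 CPM in the mutant, at least 75.3-fold higher (46.3 without WT replicate 2, 49.3 without WT replicate 3), and TrB0212C rose from 1.14 ± 0.64 to 108 ± 12.5 CPM (log2 fold change 6.53 ± 0.27 SE, adjusted p = 1.1e-10). TrF0330C fell from 119 ± 62.4 CPM to 1 read in the 3 mutant libraries, a pooled ratio of 3490 (95% counting interval 626 to 138000). The ratio was 2200 without mutant replicate 2, and at least 798 without mutant replicate 1, which held the read. TrE0746W was at least 1180-fold lower (746 without mutant replicate 2). Here 3635 genes changed, 1773 higher and 1862 lower, with 604 at least 2-fold higher and 419 at least 2-fold lower. The balance of directions depended on scaling: 48.8% of the changed genes were higher with TMM factors, 54.7% with DESeq2 and 62.6% with library totals alone.

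The interaction of the Δ80186 deletion with light asked which genes respond to light differently in the mutant. TrB1415W rose from 97.2 ± 4.75 to 1330 ± 32.7 CPM in WT, but stood at 102 ± 3.05 in darkness and 142 ± 17.6 in light in the mutant (interaction −3.30 ± 0.12 SE on the log2 scale, adjusted p = 3.5e-12). TrF0367C went from 1.2 ± 0.313 to 33 ± 0.41 CPM in WT and from 1.55 ± 0.218 to 0.369 ± 0.118 CPM in the mutant (−6.84 ± 0.32 SE, adjusted p = 7.9e-11). It had 3 to 5 reads per library in the mutant in light, too few for this SE to give its precision. Among genes lowered by light in WT, TrE0110C went from 626 ± 41 to 2.95 ± 0.17 CPM in WT and from 53.8 ± 5.75 to 14.9 ± 1.06 CPM in the mutant (5.86 ± 0.20 SE, adjusted p = 3.5e-12). TrF1060W went from 850 ± 22 to 52.8 ± 1.52 CPM in WT and from 348 ± 9.55 to 156 ± 16.3 CPM in the mutant (2.85 ± 0.11 SE, adjusted p = 1.5e-11). The interaction was called for 3798 genes, 1857 positive and 1941 negative, but 2165 positive and 1813 negative with DESeq2. It was at least 2-fold for 747 positive and 735 negative genes. In 585 genes light acted in opposite directions in WT and the mutant, past the threshold in both at any fold. Of the genes changed at least 2-fold by light in WT, 72 of 775 raised and 59 of 1407 lowered ones were called in the opposite direction in the mutant.

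The interaction of the Δ21168 deletion with light asked the same of the second mutant. TrF1049W fell in light in WT, from 1590 ± 158 to 144 ± 16.4 CPM, and was at 48.2 ± 2.45 in darkness and 102 ± 12.3 in light in the mutant (interaction 4.55 ± 0.16 SE, adjusted p = 1e-11). TrG0897W, one of the abundant transcripts, went from 5950 ± 215 CPM in darkness to 1280 ± 102 in light in WT. In the mutant it was at 510 ± 68.3 CPM in darkness and at 1170 ± 72 in light (3.42 ± 0.13 SE, adjusted p = 1.4e-11). TrF0182C rose from 86.7 ± 9.05 to 212 ± 22.5 CPM in WT and went from 129 ± 12.4 to 29.8 ± 3.84 CPM in the mutant (−3.40 ± 0.15 SE, adjusted p = 5.3e-11). TrD1302W took a similar course, from 51.8 ± 8.95 to 112 ± 8.12 CPM in WT and from 129 ± 6.71 to 30.5 ± 3.92 CPM in the mutant (−3.18 ± 0.15 SE, adjusted p = 1.8e-10). The interaction was called for 2778 genes, 1325 positive and 1453 negative, and was at least 2-fold for 547 positive and 490 negative genes. With library totals in place of TMM factors, 59.3% of the called genes were positive, against 47.7%. Light acted in opposite directions, past the threshold in both strains at any fold, in 323 genes. Of the genes changed at least 2-fold by light in WT, 48 of 775 raised and 32 of 1407 lowered ones were called in the opposite direction in this mutant.

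**Figure D3:**
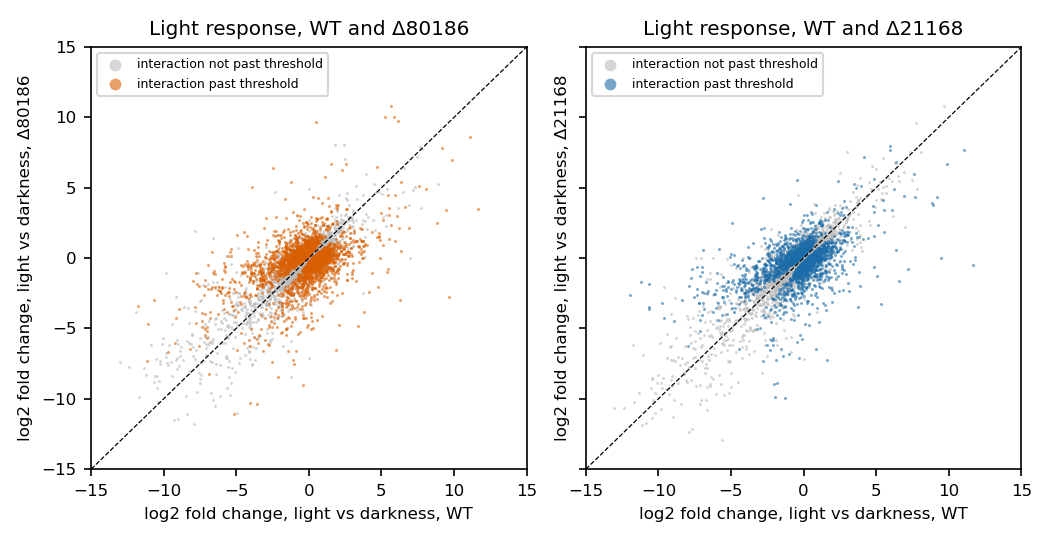
Log2 fold change of light against darkness in WT (horizontal axis) and in each mutant (vertical axis) for the 9079 genes, with coloured points where the interaction had an adjusted p under 0.05 and a dashed line of equal response. Pearson's r across genes was 0.71 for WT and Δ80186 and 0.78 for WT and Δ21168, and folds of genes with few or 0 reads in a group depend on the prior count of the fit.

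The size of the light response was compared with gene sets chosen in the third strain, whose libraries entered neither side of the comparison. This was added after the data were seen. The 664 genes raised at least 2-fold by light in Δ21168 had a mean level 1.46 ± 0.04 (SE) higher in light in WT and 0.73 ± 0.03 higher in Δ80186, on the log2 CPM scale with a prior count of 2. The 1298 genes lowered by light in Δ21168 changed by −2.16 ± 0.09 in WT and by −1.73 ± 0.04 in Δ80186. With the 560 genes raised by light in Δ80186, the response was 1.22 ± 0.07 in WT and 0.79 ± 0.04 in Δ21168. With the 1213 lowered genes it was −2.11 ± 0.08 and −1.87 ± 0.06. The difference of the mutant from WT was −0.73 ± 0.05 for raised and 0.42 ± 0.10 for lowered genes in Δ80186. In Δ21168 it was −0.43 ± 0.08 and 0.24 ± 0.10. Each of these 4 differences was more than 2 SE from 0. The choice in the third strain favours a larger response in WT, since either mutant was more like WT (r = 0.71 for Δ80186, 0.78 for Δ21168) than like the other mutant (0.65). The levels in darkness differed too. The raised set of Δ80186 differed from WT by −0.14 ± 0.02 in darkness and −0.87 ± 0.04 in light, and the lowered set by 0.40 ± 0.03 and 0.82 ± 0.10. For Δ21168 the raised set differed by 0.22 ± 0.04 in darkness and −0.21 ± 0.07 in light, and the lowered set by 0.11 ± 0.07 and 0.35 ± 0.08. Thus a higher level in darkness made up part of the smaller response of the raised set in Δ21168, but not of the other 3 sets. The 1066 genes raised at least 2-fold by light in WT or in Δ80186 changed by 1.4 ± 0.05 in WT and by 1.07 ± 0.02 in Δ80186, and the 1801 genes so lowered by −2.06 ± 0.08 and −1.77 ± 0.05. With the same choice in WT or in Δ21168, the 1055 raised genes changed by 1.49 ± 0.04 in WT and 1.28 ± 0.03 in Δ21168 (difference −0.21 ± 0.05), and the 1821 lowered genes by −2.07 ± 0.09 and −1.82 ± 0.07 (0.25 ± 0.11).

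**Figure D4:**
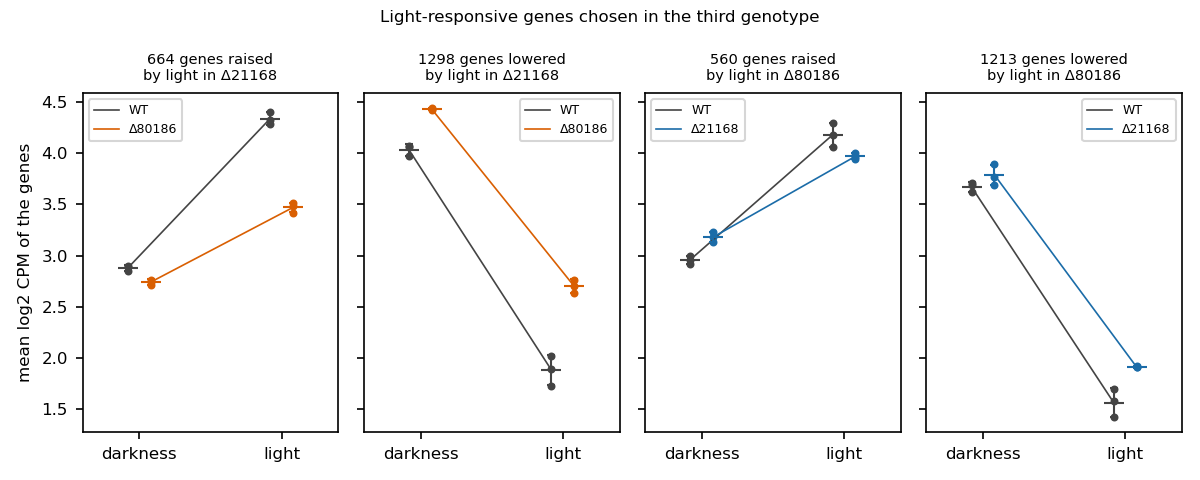
Mean log2 CPM (vertical axis) of 4 gene sets in darkness and in light, with points for the 3 libraries of a group and a horizontal mark and bar for mean ± SD. Each set was chosen from the light response of the third strain. The line of each mutant is less steep than that of WT, with light-minus-darkness differences of 0.73 against 1.46 for the first set.

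The responses to the deletions were compared within each light condition. In darkness 937 genes were higher and 746 lower in both mutants, and 267 changed in opposite directions. Independent lists of these lengths would share 381 higher and 363 lower genes and hold 744 in opposite directions. Without WT replicate 2, 174 genes changed in opposite directions, against 550 for independent lists. In light 741 genes were higher and 734 lower in both, against 497 and 571 for independent lists, and 921 changed in opposite directions, against 1065. Pearson's r of the fold changes across genes, which are not independent replicates, was 0.51 in darkness and 0.26 in light. Unchanged groups simulated against the same WT libraries gave an overlap of 0 genes in all 20 simulations of each condition, and mean r of 0.02 and 0.07. No gene was changed in these simulations, so hardly any could be called, and the overlap of 0 follows from the design. It does not show how much the shared WT libraries add to the observed overlap. The covariance was 0.491 in darkness and 0.334 in light, against simulated means of 0.001 and 0.005. The simulated libraries were drawn from the means of these WT libraries, so error in those means was not part of the simulated r and covariance. With a WT library left out it was 0.534 to 0.567 in darkness and 0.319 to 0.525 in light. In light r was then 0.243 to 0.347, and both values were highest without WT replicate 3. Without this library the covariance in light, 0.525, came close to the 0.534 to 0.567 in darkness but stayed lower. The r in light, 0.347, also stayed below the 0.514 to 0.533 in darkness with a WT library left out. Both mutants were compared with the same 3 WT libraries, too few to divide, so part of the excess may come from these shared controls.

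Each deletion response was also compared between the light conditions, which share no library. For Δ80186, 869 genes were higher and 737 lower in both darkness and light, against 451 and 473 for independent lists, and 486 changed in opposite directions, against 926. For Δ21168, 848 genes were higher and 910 lower in both, against 419 and 438, and 431 changed in opposite directions, against 857. All 6 libraries of Δ21168 were in the other library series. A batch shift that is the same in darkness and light would also give such an excess and cannot be told apart here. Pearson's r across genes was 0.38 and 0.42.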

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

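The comparison of light-responsive gene sets, the choice of genes in WT or Δ80186, the tests of a library batch and the thinning of reads were chosen after the results were seen.

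Light responses that differed between a mutant and WT, by a test of the interaction itself, drew attention to 3798 genes for Δ80186 and 2778 for Δ21168. The named genes of the first were TrE0110C with an interaction of 5.86, TrF1060W with 2.85, TrB1415W with −3.30 and TrF0367C with −6.84 on the log2 scale. Those of the second were TrF1049W with 4.55, TrG0897W with 3.42, TrF0182C with −3.40 and TrD1302W with −3.18. Of 100 splits of the genotypes within each light condition, the real included, 1 gave as many genes as the real split for Δ80186, where the highest other split gave 3634. For Δ21168, 2 of 100 did, and the highest other split gave 4679. That split exchanged the whole genotypes in 1 light condition only, so it measured the sum of both deletion effects. The split with 3634 genes kept the genotypes whole in 1 light condition only, so it too held a deletion effect. Splits that mixed the genotypes in both light conditions carry the deletion effect as spread within groups, so their 0 genes say little about chance. Both shares are under 0.05 but for this reason overstate how firmly chance is excluded.

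For the 7 pairwise comparisons, 6 libraries allow 10 splits, too few for a share under 0.05. In each, 1 split of 10, the real one, gave as many genes. The highest other split gave 97 genes against 4282 for Δ21168 in darkness, 52 against 5469 for light in Δ21168, and 0 in the 5 other comparisons, whose real counts were 3154, 5328, 3635, 5543 and 4836. Every other split mixed the groups compared and so carried the real effect as spread within groups. Their low counts therefore say little about chance.

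The light response was smaller in Δ80186 than in WT, and choosing genes by their response in WT favours this result. With genes chosen in Δ21168, the response in Δ80186 was 50.1% of that in WT for raised and 80.5% for lowered genes, which argues against such selection as the whole cause. Genes so chosen favour the strain more like Δ21168, which was WT (r = 0.78 across genes, against 0.65 for Δ80186). Genes changed at least 2-fold by light in WT or in Δ80186, a rule applied alike to both, were also used. They still gave 76.8% for raised (difference from WT −0.32 ± 0.06 SE) and 85.9% for lowered genes (0.29 ± 0.10). Likeness to Δ21168 is thus argued against as the whole cause, and the size of the gap depended on the choice. This rule used the libraries that were compared, so it does not remove selection through WT. More genes passed it in WT (775 raised and 1407 lowered) than in Δ80186 (560 and 1213). A general shift of the scaling would move raised and lowered genes the same way, but with genes chosen in Δ21168 the difference from WT was −0.73 ± 0.05 for raised and 0.42 ± 0.10 for lowered genes, of which the latter were already 0.40 ± 0.03 above WT in darkness. Δ21168 had a smaller response too. With genes chosen in WT or in Δ21168, it was 85.9% of that in WT for raised and 88% for lowered genes. The gap was thus not particular to Δ80186. Both mutants were set against the same WT libraries, and whether these made part of it was not tested. A weaker light response through the loss of TR80186 may be a biological explanation, as a hypothesis found and tested on the same libraries.

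The differences between Δ21168 and WT coincide with a separate series of library numbers. A batch shift that is the same in darkness and in light cancels in the interaction by construction of the contrast, so it cannot account for the interaction of the 2778 genes called. A batch shift that differs between the light conditions was not tested. For the 1275 genes changed in the same direction in both light conditions without a called interaction, a batch and the deletion cannot be told apart, since all 6 libraries of the mutant are in the other series. The lower depth of these libraries was also tested: after thinning to the smallest library, 4030 genes changed in darkness and 89.9% of the 4282 remained, which argues against depth. The deletion and a library batch both remain possible for the genes changed in both light conditions.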

How the results depend on the processing

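All 141 counts under an alternative, the mutant overlaps in the same direction included, were within 1.5 times the main count. Overlaps in opposite directions were not among them. In darkness this overlap fell from 267 to 174 genes without WT replicate 2. Leaving out each library in turn gave 2460 to 2755 genes for Δ80186 in darkness (main 3154) and 2353 to 3063 for the Δ21168 interaction (main 2778). The fit of only the groups compared gave 3133 genes for Δ21168 in darkness (main 4282) and 4162 for light in Δ21168 (main 5469). For the Δ21168 interaction it gave 2190 (main 2778). All of these comparisons include the dark libraries of Δ21168, the group with the widest spread. For Δ80186 the same fit gave more genes, 3447 in darkness (main 3154) and 5706 in light (main 5328). It gave 5392 for light in Δ80186 (main 4836) and 4406 for the Δ80186 interaction (main 3798). Which mutant had more changed genes in darkness, and which in light against darkness, thus turned with this fit. Of 516 values of named genes, 515 kept direction and call, 0 reversed and 1 lost its call, TrG0638W for Δ80186 in darkness (adjusted p 0.067 with only the groups compared, range over alternatives 4.2e-07 to 0.067). Library totals without TMM, chosen after seeing the data, raised the share of higher genes to 62.6% for Δ21168 in light and 59.3% for its interaction. Which direction held more changed genes turned under at least 1 alternative in every comparison but Δ80186 in darkness. In light against darkness in each strain it turned with DESeq2, RLE factors, no filter and only the groups compared. For Δ21168 in darkness it turned with only the groups compared, at 1479 higher and 1654 lower genes, and with the replicate block, at 2098 and 2112. There it also turned without WT replicate 3, without mutant replicate 1 and without mutant replicate 3. Lower bounds of folds shrink by construction when a library with 0 reads is left out.

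The replicate numbers did not pair the samples: in 0 of 7 comparisons was every same-number correlation over 0.1 (range −0.24 to 0.45), and in none did every library correlate best with its own number. With the replicate block, 5510 genes changed by light in WT (main 5543) and 3036 for Δ80186 in darkness (main 3154). The gene list tests, with their alternatives, were not run because 0 identifiers matched the reference table. Depth limits genes with few reads, where folds against 0 reads are only lower bounds.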

Other observations

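The counts of runs, the levels of runs, the search for identifiers without reads, the shuffle of end genes and the tests at distance 5 were chosen after the data were seen.

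Several named identifiers lay in runs of consecutive numbers that changed together at least 2-fold. That the numbers follow the order along chromosomes is assumed from their form. These runs were described with the summed CPM of their genes, which abundant members lead, so a sum need not follow each gene. The runs of TrD0072C and TrA1899C were those of light against darkness in WT. Those of TrB0848C and TrE0110C were of Δ21168 against WT, in light and in darkness. A run of 6 genes that holds TrD0072C was at 12.6 ± 2.45 CPM in WT in darkness, 377 ± 7.53 in Δ80186 and 122 ± 11 in Δ21168, and at 0.543 ± 0.233, 0.588 ± 0.23 and 3.51 ± 1.33 CPM in light. For each mutant against WT in darkness, the run held only 4 of these genes. A run of 4 with TrB0848C was at 64.5 ± 3.66 CPM in WT in darkness, 157 ± 14.1 in Δ80186 and 52.5 ± 6 in Δ21168. In light it had 0 reads in all 3 WT libraries, 0 to 9 reads in Δ80186 and 83 to 138 reads in Δ21168. A run of 6 with TrA1899C stood at 780 ± 67.4 CPM in darkness and 46.8 ± 3.08 in light in WT, and at 815 ± 145 and 405 ± 44 CPM in Δ80186 and 434 ± 37.5 and 32.7 ± 7.52 CPM in Δ21168. In darkness TrA1899C itself was higher in Δ21168, at 81.4 ± 13.2 CPM against 1.73 ± 0.837 in WT, so other members led the sums. A run of 4 with TrE0110C was at 1180 ± 56 CPM in WT in darkness, 311 ± 17.6 in Δ80186 and 120 ± 16.7 in Δ21168, and at 97 ± 3.33, 192 ± 5.86 and 81.9 ± 4.56 CPM in light.

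Runs of at least 4 genes numbered 44 for light in WT, 39 for light in Δ80186 and 35 for light in Δ21168, with a longest run of 8 genes. The comparisons of mutants with WT held 8, 11, 22 and 7 such runs (Δ80186 in darkness and light, then Δ21168 in darkness and light).

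Pairs of identifiers changed in the same direction at 1.46 to 1.97 times the permuted mean at distance 2, 1.17 to 1.71 times at distance 3, 1.23 to 1.48 times at distance 5, 1.11 to 1.30 times at distance 10 and 0.96 to 1.26 times at distance 50. All 1000 permutations were exceeded in 7, 4, 3, 3 and 0 of the 7 comparisons. At distance 50 the permutation p was under 0.05 in 3 comparisons before adjustment over the 7 and in 0 after it (lowest adjusted p 0.082). At distance 5 the adjusted p was 0.0023 to 0.016. The difference of the ratio at distance 5 from that at distance 50 had an adjusted p of 0.0023 in the 3 comparisons of light with darkness, 0.04 for Δ21168 in light and 0.12 to 0.44 in the other 3 comparisons. Where the far ends of pairs around a gene that did not change that way were shuffled, the pairs were 1.29 to 1.91 times the shuffled mean. The permutation p was 0.001, the smallest that 1000 permutations give, in the 3 comparisons of light with darkness, 0.009 to 0.012 in 3 mutant comparisons and 0.13 for Δ80186 in darkness.

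Neighbouring identifiers changed together more often than permuted ones: pairs at distance 1 exceeded all 1000 permutations in 7 of 7 comparisons, at 2.03 to 3.02 times the permuted mean. Noise of genes with few reads is argued against, since the excess held in 7 of 7 comparisons among genes with a mean CPM of at least 10. Reads shared between overlapping neighbours are argued against as the whole cause for light against darkness: at distance 5, where genes are assumed not to overlap, the pairs (1.38 to 1.48 times the permuted mean) and the difference of their ratio from that at distance 50 exceeded every permutation in 3 of 3 comparisons. For the mutants against WT, shared reads stay open, since this held in 0 of 4 comparisons (ratios of 1.23 to 1.36 at distance 5 and 0.96 to 1.26 at distance 50), as does their part at short distance in all comparisons: every permutation was exceeded in 4 of 7 at distance 3, by pairs around a gene that did not change that way in 0 of 7 (a count that clustering of any cause lowers), and in shuffles of the far ends in 3 of 7, although p was under 0.05 in 6 of 7, 3 of them mutant comparisons, which goes against shared reads. The p-values of these shuffles were not adjusted, and the comparisons share libraries, so they are not separate pieces of evidence and do not settle the question. Regional regulation may contribute, and no biological explanation was tested.

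A hypothesis is that TrD0367C and TrE0746W are the deleted loci TR80186 and TR21168. A search for identifiers with at most 3 reads in every library of a mutant and at least 10 CPM in the 12 others returned 1 for Δ80186 and 1 for Δ21168. As the hypothesis arose from this loss of reads, the search does not test it. The tested identifiers within a distance of 2 of TrE0746W had log2 fold changes of 0 to 0.28 against WT in darkness and 0 to 0.18 in light, of which 0.28 ± 0.11 (SE) passed the threshold (edgeR adjusted p = 0.034). Those near TrD0367C had −0.98 ± 0.14, −0.50 ± 0.08 (both past the threshold) and −0.10 ± 0.11 (SE) in darkness and 0.19 to 0.26 in light, of which 0.25 ± 0.08 passed (adjusted p = 0.014). The match remains open because neither the files nor the reference table pair these numbers.

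Replicate 1 of Δ21168 in darkness had rank correlations of 0.959 to 0.967 with the libraries of Δ80186 in darkness, where the other two libraries of its group had 0.942 to 0.949. It had 0 reads of TrE0746W. The common biological coefficient of variation was 0.235 in Δ21168 in darkness and 0.077 to 0.13 in the other groups. The rows of the mating type locus MAT1-1 held 5 reads of mat1-1-1 in 4 of 18 libraries, at most 2 in a library, and 0 reads of mat1-1-2 and mat1-1-3.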
